A study of Homo sapiens with 12 samples.

How the data were processed

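RNA from MCF-7 cells treated with DMSO or dioxin was measured on Affymetrix HG-U133A and HG-U133B arrays, in which short oligonucleotide probe sets capture biotin-labelled target, per the labels. Samples were grouped by treatment and array type from their titles, with 3 arrays per group, and the replicate is the experiment number in the title. No columns held identical values.

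The deposited tables give 1 intensity per probe set and array on a linear scale. The summary algorithm, its software and the scaling target are not given in the sources used here. The mean after trimming 2 percent at each end was 2501 on every array to 4 digits, so the authors' intensities were already scaled between arrays and were used as deposited. No detection calls were used here, so probe sets were kept or left out by brightness only. The deposited experiment descriptions hold no expression values; their chip type, chip lot, fluidics module and scan day were read to find batches. The chip type matched the labels on all 6 arrays of each array type. Each experiment had its own chip lot and its own scan day on each array type, shared by both of its treatments, so a block by lot or day is the block by experiment number. On U133A each fluidics module held 1 treatment and each treatment spanned 2 modules, so the module was fitted as a random block with duplicateCorrelation, and lists were then tested with cameraPR on its t statistics. On U133B 2 modules held both treatments, so the module was fitted as a block, which leaves 1 residual degree of freedom.

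Probe sets were named from GEO's platform annotation, with symbols checked through gene identifiers against a table of the GRCh38.p14 assembly. Of 22215 U133A probe sets other than 68 controls, 19065 had 1 gene symbol, 1043 several and 2107 none. Of 22577 on U133B, 15426 had 1, 554 several and 6597 none. No gene was named from a probe set with several symbols. No coordinates are given, since the files name no genome build.

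Values were transformed as log2(signal + 16), so fold changes of dim probe sets are understated. Control probe sets and those under the 30th percentile of mean log2 signal over the 6 arrays were left out of the tests. Each array type was tested on its own with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a mean-variance trend, two-sided. Benjamini-Hochberg adjustment ran over the tested probe sets of the array type, with a threshold of 0.05. An SE is that of the moderated fit unless it is said to be across genes, and the SE beside a blocked p is that of the blocked fit. Group means and SDs are of the signals. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

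The design, the alternatives, 22 gene lists and the rule for named genes were set before the data were examined. The rule took, per array type, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and changed in the same direction in all 3 experiments, each by its most changed probe set. Where fewer than 5 genes passed, it took the 10 smallest p instead. It added, with the brightest probe set of each, CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1, AHR, ARNT, ESR1, TFF1, PGR, CCND1, CXCR4 and CXCL12, and up to 4 passed members of each list, or the 2 with the smallest p where none passed. After the data were seen, the same rule was applied to the fit with the replicate block, which added the genes said to have passed in that fit, and up to 6 members of each list past with the block, over all tested probe sets or over the list alone, were named too. CYP1A1 and CYP1B1 served as the check of the treatment labels. Genes compared between array types were those passed with the block on U133A, by their most changed probe set there and the brightest on U133B.

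Gene lists were tested with camera (preset correlation 0.01) on U133A, with 1 probe set per gene, the brightest, and Benjamini-Hochberg adjustment over the 22 lists, each with at least 5 measured genes. Counts of list members take the brightest U133A probe set, or the U133B one for a gene measured there only. The estimated correlation and fry were alternatives.

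The experiment numbers were checked as a pairing. The deviations of DMSO and dioxin arrays from their group means correlated at 0.76, 0.34 and 0.57 for experiments 1, 2 and 3 on U133A and at 0.63, 0.37 and 0.45 on U133B, all above the limit of 0.1. Some arrays of different number passed it too. DMSO 2 with dioxin 3 gave 0.26 on U133A and 0.101 on U133B, and DMSO 3 with dioxin 2 gave 0.11 on U133A. Each same-numbered r was the highest of both its arrays, so the numbers were taken to pair the samples. The labels say that the experiment was repeated; what made arrays of 1 experiment alike, a culture or the shared lot and scan day, is not given.

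The scripts were tested on simulated data in which 200 probe sets per array type were changed, with the real spread between experiments. On U133A the fit without the block found 3 percent of changes of 1 on the log2 scale and 39 percent of changes of 2, and the blocked fit 71 and 90 percent, with 10 false calls among 171. On U133B the shares were 0 and 11 percent without the block and 39 and 74 percent with it, with 8 false calls among 121. With the fluidics module in the fit the shares were 2 and 38 percent on U133A and 0 and 0 percent on U133B. With 1 list shifted and genes simulated as independent, camera found that list and 0 of 21 others. In the data genes within lists were correlated, with an estimate of 0.49 for the NRF2 list. The 0 therefore does not measure false list calls in the data.

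Alternatives were other pseudocounts, filters, between-array normalizations and variance models, the replicate block, a minimum fold change of 1.5, leaving out each array and each experiment, and for lists other set tests and the mean of a gene's probe sets. Blocked fits with other pseudocounts, filters, normalizations and variance models, with the minimum fold change and without each experiment were added after the data were seen. So were the fits with the fluidics module and the recomputed agreement of the array types. Blocked counts were not recomputed without single arrays.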

Results

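RNA from MCF-7 cells, an oestrogen receptor positive human breast cancer line, was compared between cells treated with 100 nM dioxin for 16 h and cells treated with the solvent DMSO alone, whose exposure time the labels do not give. Dioxin is a ligand of the aryl hydrocarbon receptor (AHR), a transcription factor that pairs with ARNT and switches on genes of foreign-compound metabolism. The comparison asks which transcripts differ in level between treated and solvent control cells. The experiment was run 3 times, and each treatment was measured on a U133A and a U133B array in each experiment, giving 3 arrays per treatment on each array type. The labels do not say whether the 3 experiments were separate cultures, so p-values measure only the spread between these samples, which may be technical. The median signal per array lay between 686 and 1146 on U133A and between 987 and 1441 on U133B, and the highest signals were 119307 and 356623. The number of arrays limits the precision of every value. On U133A the arrays of experiment 1 correlated with those of experiments 2 and 3 at r = 0.879 to 0.904, and arrays of experiments 2 and 3 with each other at 0.932 to 0.958, while on U133B these ranges were 0.740 to 0.767 and 0.855 to 0.878. Ratios of 3' to 5' control signals, which rise as RNA degrades, lay between 0.791 and 0.991 for GAPDH and between 0.966 and 1.11 for ACTB. On U133B the GAPDH ratio was 0.951 ± 0.035 (SD, n = 3) with dioxin and 0.861 ± 0.020 with DMSO (two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 can give). The ACTB ratio there had a mean of 1.05 with dioxin and 0.997 with DMSO (exact permutation p = 0.2). Neither test used the pairing, and within each experiment both ratios on U133B were higher with dioxin.

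Dioxin raised the transcripts of 5 genes on U133A, all known targets of AHR. CYP1A1, a cytochrome P450 enzyme that oxidises aromatic hydrocarbons, went from a signal of 212 ± 169 (SD, n = 3) with DMSO to 65013 ± 6903 with dioxin, a log2 fold change of 8.70 ± 0.73 (SE, limma adjusted p = 0.00535). CYP1B1, a related enzyme that also hydroxylates oestradiol, rose on all 4 of its probe sets, by 2.23 to 4.09 on the log2 scale. ALDH3A1, an aldehyde dehydrogenase, rose by 3.18 ± 0.31 (adjusted p = 0.0116). SLC7A5, the light chain of a transporter of large neutral amino acids, rose by 2.47 ± 0.27 (adjusted p = 0.0206), from a signal of 5556 ± 1625 to 30542 ± 7846. TIPARP, an ADP-ribosyltransferase that represses AHR, rose by 1.58 ± 0.18 (adjusted p = 0.0271).

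These genes were 8 probe sets higher and 0 lower among the 15550 tested, and all 8 moved in the same direction in each of the 3 experiments. At an unadjusted p under 0.05 there were 322 probe sets in limma, and 1580 with the experiment number as a block, against 777.5 expected by chance. The fit without the block thus gave fewer small p-values than chance would. It leaves differences between experiments in the residual spread, with a median SE of 0.302 against 0.181 with the block, so its p-values are too large for paired samples. The CYP1A1 signal with DMSO was 339, 275 and 20.4 in experiments 1, 2 and 3, near the bottom of the arrays, so its fold of 416 is on the log2(signal + 16) scale and depends on that added value. With a variance prior that ignored signal the count of 8 became 0, and with median centring 4. It was 5 without DMSO replicate 2, 1 without dioxin replicate 2, 0 without dioxin replicate 3, 0 without experiment 2 and 1 without experiment 3. The TIPARP call was also lost without DMSO replicate 3 (adjusted p = 0.0522) and without experiment 1 (0.135). Over the 19 settings run the log2 fold changes lay between 7.65 and 9.30 for CYP1A1, 2.91 and 3.46 for ALDH3A1, 2.21 and 2.69 for SLC7A5 and 1.47 and 1.69 for TIPARP. Each fluidics module, the unit that stains and washes an array, held 1 treatment only on U133A. In each experiment the dioxin array had the higher module number, so module and treatment cannot be told apart within a pair there. With the module as a random block the count was 6 and TIPARP did not pass (adjusted p = 0.0864). A random block cannot remove a module difference that goes with treatment, so this count is not corrected for one.

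**Figure D1:**
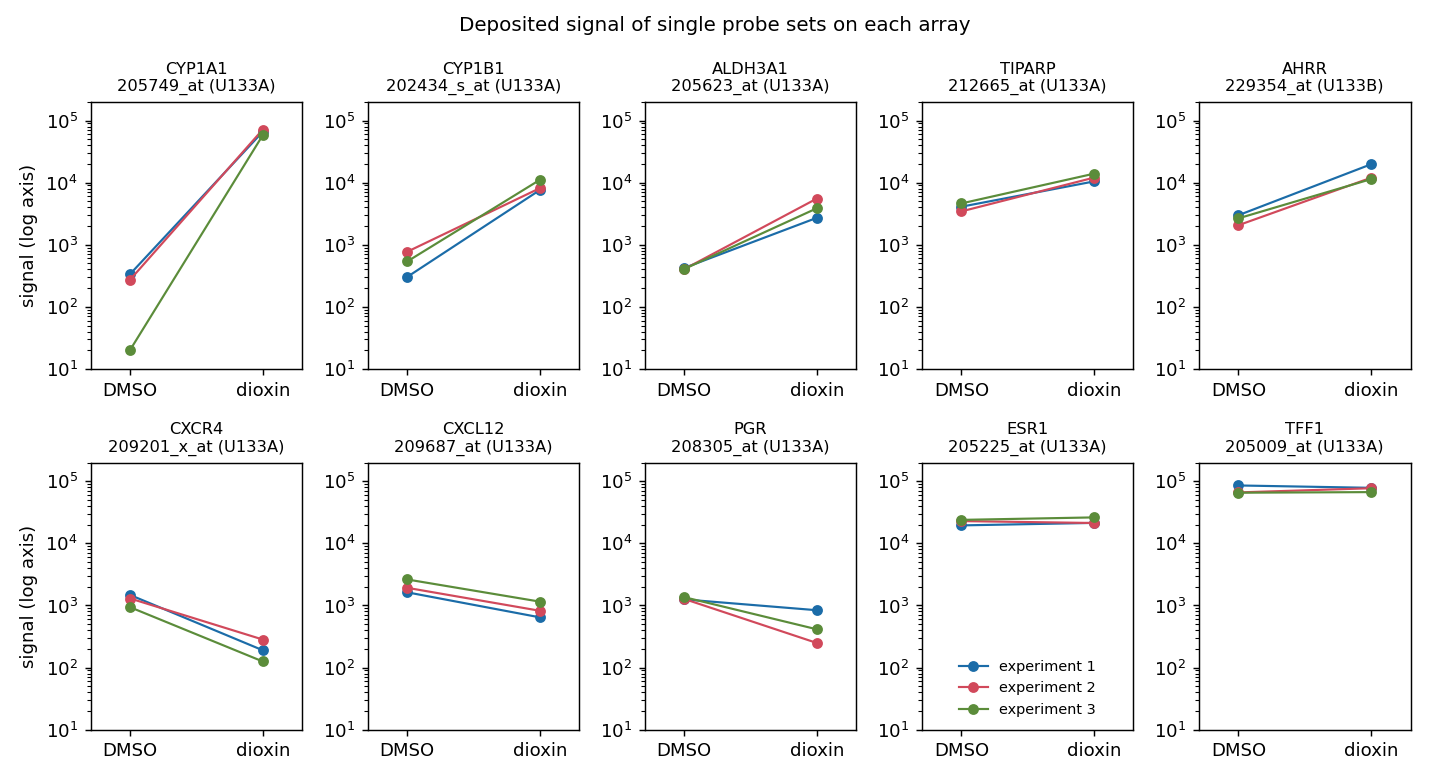
Deposited signal (log axis, arbitrary units) of single probe sets with DMSO and with dioxin, where each point is an array, each colour an experiment, and each line joins the DMSO and dioxin arrays of an experiment. CYP1A1 lay between 20.4 and 339 with DMSO and between 57761 and 71504 with dioxin, while ESR1 lay between 19476 and 26192 on all 6 arrays.

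More genes rose once the experiment number was taken as a replicate block. ALDH1A3, which makes retinoic acid from retinaldehyde, rose by 3.57 ± 0.34 (SE, n = 3, blocked adjusted p = 0.00572), from a signal of 714 ± 757 to 6332 ± 5110. SLC7A11, the cystine and glutamate exchanger, rose by 1.81 ± 0.24 on 1 of its 3 probe sets (blocked adjusted p = 0.0273), with 1.37 and 1.11 on the others, which did not pass. PPARG, a nuclear receptor of fat cell formation, rose by 1.73 ± 0.26 (blocked adjusted p = 0.0427), and TSKU, a secreted leucine-rich protein, rose by 1.60 ± 0.12 (blocked adjusted p = 0.00151). DDIT4, an inhibitor of mTORC1 signalling, rose by 1.41 ± 0.12 (blocked adjusted p = 0.00309). With the block 59 probe sets passed in limma on U133A, 37 higher and 22 lower, and they included the 8 that passed without it. They belonged to 29 genes with higher and 17 genes with lower signal, plus 7 probe sets without a single gene name. All 59 moved in the same direction in the 3 experiments, as did 33.4 percent of all probe sets tested on U133A. The blocked fit favours probe sets whose differences are alike between experiments, so this is largely built in.

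Among genes that fell in the blocked fit and not without it, CXCR4, the receptor of the chemokine CXCL12, went from a signal of 1234 ± 273 (SD, n = 3) to 200 ± 79 on 1 probe set, a log2 fold change of -2.58 ± 0.33 (SE, blocked adjusted p = 0.0225). The dioxin signal of that probe set lay near the bottom of the arrays, so the size of its fold depends on the value added before log2. Its other probe sets gave -0.97 (adjusted p = 0.262) and -0.48 (adjusted p = 0.337) in that fit and did not pass. CXCL12 itself gave -1.23 ± 0.18 on the probe set that passed (blocked adjusted p = 0.0362) and -0.89 ± 0.14 on its brighter one, which did not (adjusted p = 0.0511). RET, a receptor tyrosine kinase, passed on 2 of 3 probe sets at -1.52 ± 0.20 and -0.80 ± 0.11 (blocked adjusted p = 0.0274 and 0.0288). NPY1R, a neuropeptide Y receptor, was at -1.40 ± 0.16 (blocked adjusted p = 0.0143), and the kinase gene SGK1 at -1.45 ± 0.21 (blocked adjusted p = 0.0373), which also passed without the block when dioxin replicate 1 was left out (adjusted p = 0.0429). The transcription factor genes HEY2, MYBL1 and MYB fell with log2 fold changes of -1.38, -1.23 and -1.19, and so did the glucuronosyltransferase gene UGT2B15 and the sulfotransferase gene HS3ST3A1, both at -1.35. The blocked count of 59 became 39 with no filter on dim probe sets, 0 with a variance prior that ignored signal, and 199 without experiment 1.

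**Figure D2:**
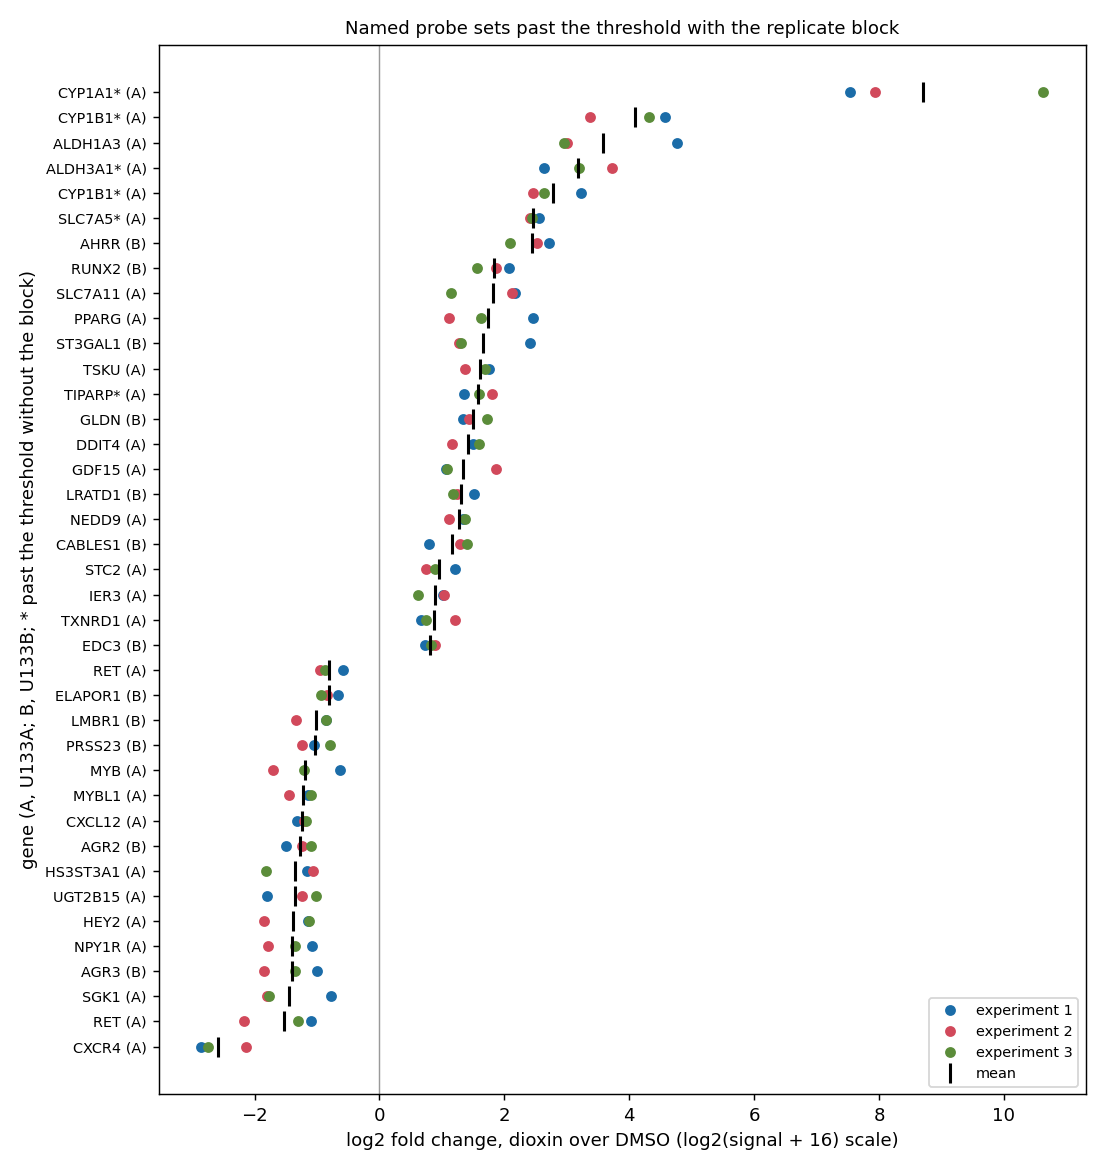
Log2 fold change of dioxin over DMSO in each experiment (coloured points) and their mean (black bar) for the probe sets taken by the naming rule that passed with the replicate block; A and B give the array type, and an asterisk marks those that also passed without the block. For each probe set all 3 points lie on the same side of 0, which the naming rule asked of the largest rises and falls. The means run from -2.58 for CXCR4 to 8.70 for CYP1A1.

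On U133B the gene with the smallest p was AHRR, the AHR repressor, whose signal was 2566 ± 469 (SD, n = 3) with DMSO and 14315 ± 4645 with dioxin. Its log2 fold change of 2.44 ± 0.30 (SE) did not pass without the block (limma adjusted p = 0.166) and passed with it (adjusted p = 0.00189). In the blocked fit RUNX2, a transcription factor of bone formation, rose by 1.83 ± 0.18 (adjusted p = 0.0108), while its other tested probe sets gave -0.37 on U133B and 0.30 on U133A and did not pass. The sialyltransferase gene ST3GAL1 rose by 1.67 ± 0.21 (adjusted p = 0.0293), and GLDN went from a signal of 4099 ± 931 to 11447 ± 1201 (adjusted p = 0.0108). CABLES1 and EDC3 also rose with the block, at 1.16 and 0.81, as did LRATD1 at 1.31 on 1 of 5 probe sets, the others lying between -0.19 and 0.24. AGR3 and AGR2, protein disulfide isomerase relatives made by secretory epithelium, fell with log2 fold changes of -1.40 ± 0.15 (adjusted p = 0.0166) and -1.28 ± 0.12 (adjusted p = 0.0108), while AGR2 on U133A gave -0.25 (adjusted p = 0.28). PRSS23, LMBR1 and ELAPOR1 fell with the block at -1.03, -1.01 and -0.81. Modules 1 and 2 of the fluidics station each held 1 array per treatment, from different experiments. Within them 10 of the 12 probe sets that passed with the block kept their direction in both modules, among them AHRR at 2.16 and 2.45. The other 2 turned sign in 1 module, PRSS23 at -2.25 and 0.21 and ELAPOR1 at 0.14 and -1.91, and these differences have no test. They pair anew the arrays of experiments 2 and 3, which also went into the blocked calls. A kept direction within modules is therefore largely built in. Between experiments 2 and 3 the modules of the treatments were swapped, so a steady difference between modules 1 and 2 would turn sign there. All 12 probe sets changed in the same direction in the 3 experiments, with AHRR at 2.53 and 2.09 in experiments 2 and 3. This argues against such a difference as the cause of the 12 calls. In experiment 1 dioxin was on module 4 and DMSO on module 3, so module and treatment cannot be told apart there.

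Of the 15804 probe sets tested on U133B, 0 passed in limma without the block, with 197 at an unadjusted p under 0.05 against 790.2 expected by chance. As on U133A this is fewer than chance would give, and the median SE was 0.468 without the block and 0.321 with it. With the block 12 passed, 7 higher and 5 lower, and 1002 had an unadjusted p under 0.05. Among the 10 genes with the smallest p without the block, PITPNM2 (1.83), GRHL3 (1.48), SLC26A2 (-1.31) and BEX5 (-1.14) passed in neither fit. The GAPDH 3' to 5' ratio on these arrays was 0.951 with dioxin and 0.861 with DMSO, without overlap. The blocked count of 12 became 4 with no filter, 4 with median centring (3 higher and 1 lower), 0 with a variance prior that ignored signal and 41 without experiment 1.

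The AHR battery shifted higher as a list, with 12 of 13 measured genes above 0 and a median log2 fold change of 0.67. Over all tested probe sets 5 of its genes were higher and 8 did not pass, among them CYP2S1 at -0.21, and EREG (0.26) and IL1B (0.67), which differed in sign between experiments. Adjusted over the list alone 7 were higher. With the replicate block 6 were higher over all tested probe sets and 9 over the list alone. NQO1, a quinone reductase, gave 0.36 ± 0.13 (SE, n = 3) on its brightest probe set, which passed over the list alone, and another of its probe sets rose by 0.69 ± 0.08 with the block (adjusted p = 0.0146). The battery had the smallest p of the 22 lists in camera (adjusted p = 5.71e-27, higher) and held with an estimated correlation (adjusted p = 0.0159), though not with the block and an estimated correlation together (adjusted p = 0.216). Camera with the preset correlation also called 2 to 6 lists in each split of the arrays that mixed the treatments. This limits every list call below. None of the 12 measured genes of the receptor complex and its cofactors passed in limma in either fit or over the list alone. AHR gave -0.07 ± 0.28, ARNT -0.22 ± 0.30, the chaperone gene HSP90AB1 0.29 and RB1 -0.33. The camera adjusted p of this list was 0.416, and 1 gene was higher over the list alone with the block without experiment 1.

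Oestrogen-induced genes shifted lower as a list, with 22 of 26 measured genes below 0 and a median log2 fold change of -0.39 (camera adjusted p = 2.08e-09, and adjusted p = 0.091 with an estimated correlation). Over all tested probe sets 0 passed, and adjusted over the list alone 1 was higher and 5 were lower. With the block MYB and RET fell and STC2, a secreted glycoprotein, rose by 0.95 ± 0.11 (SE, n = 3, adjusted p = 0.0146), and adjusted over the list alone 2 were higher and 12 lower. PGR, the progesterone receptor, gave -1.51 ± 0.45 on U133A, which passed over the list alone, and -1.13 ± 0.35 on U133B. PDZK1, a scaffold protein, gave -1.54 and passed over the list alone with the block. The oestrogen receptor gene ESR1 gave 0.05 ± 0.14 and CCND1, cyclin D1, gave -0.14 ± 0.14. TFF1, a secreted peptide, gave 0.04 ± 0.13, and -0.07 after quantile normalization. Without experiment 1 the blocked counts over all tested probe sets went from 1 higher and 2 lower to 2 and 7, and without experiment 2 the lower count was 0.

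Cell cycle genes shifted slightly lower as lists, with 23 of 24 measured genes of G1/S and replication and 22 of 24 of G2/M below 0, at median log2 fold changes of -0.21 and -0.20. The camera adjusted p was 1.52e-05 for G1/S and 3.43e-05 for G2/M, and adjusted p = 0.412 for both with an estimated correlation. In fry the adjusted p was 0.555 for both. The estimated correlations within the lists were 0.29 and 0.39, so the counts below 0 are not of independent genes. Over all tested probe sets 0 genes of either list passed in limma in either fit, and without the block 0 passed adjusted over the list alone. Adjusted over the list alone with the block, the cyclin gene CCNE2 (-0.54) and the replication genes RFC4 (-0.40) and GINS2 (-0.36) fell. No G2/M gene passed over the list alone, where the kinesin genes KIF23 and KIF20A gave -0.54 and -0.36. The 3 G1/S genes became 0 without experiment 1, 0 without experiment 2 and 1 without experiment 3. The mean of the G1/S genes on U133A was -0.22, and -0.11 without dioxin replicate 2 or without experiment 2, and the G2/M call was lost without DMSO replicate 3 (adjusted p = 0.207, mean -0.09 in place of -0.19) and without dioxin replicate 1 (adjusted p = 0.118).

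Antioxidant genes of the NRF2 pathway were higher as a list, with all 18 measured genes above 0 and a median log2 fold change of 0.37 (camera adjusted p = 7.16e-10, and adjusted p = 0.34 with an estimated correlation). Over all tested probe sets 0 passed without the block and 1 with it, TXNRD1, thioredoxin reductase, which rose by 0.88 ± 0.12 (SE, n = 3, adjusted p = 0.0273). Adjusted over the list alone the counts were 0 and 9. HMOX1, haem oxygenase, gave 0.83, 3.26 and 0.32 in experiments 1, 2 and 3, and the list mean was 0.32, 0.85 and 0.22. The blocked count over the list alone became 5 without experiment 2, that over all tested probe sets 4 without experiment 1, and the mean on U133A of 0.45 became 0.27 without experiment 2 and 0.21 without dioxin replicate 2.

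Retinoid genes were higher as a list, with 11 of 14 measured genes above 0 and a median log2 fold change of 0.51 (camera adjusted p = 0.00548, and adjusted p = 0.22 with an estimated correlation). ALDH1A3 was the 1 member that passed over all tested probe sets, with the block, where 0 passed without it. Adjusted over the list alone 1 was higher, ALDH1A3, and 1 lower, CYP26B1, which degrades retinoic acid, at -2.04 ± 0.58 (SE, n = 3). Its signal went from 707 with DMSO to 159 with dioxin, near the bottom of the arrays, so the size of its fold depends on the value added before log2. With the block 5 were higher and 1 lower over the list alone, the higher ones including DHRS3 (1.14), the receptor genes RARG (0.90) and RXRA (0.37), and STRA6 (0.79). The call was lost without dioxin replicate 3 (adjusted p = 0.0597, mean 0.47), and the U133A mean of 0.52 became 0.91 with a filter at the 50th percentile. With the block, 2 were higher over all tested probe sets without experiment 1, and 3 were higher and 2 lower over the list alone without experiment 3.

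Immediate early and growth factor genes were higher as a list, with 14 of 18 measured genes above 0 and a median log2 fold change of 0.22 (camera adjusted p = 0.0321, and adjusted p = 0.412 with an estimated correlation). IER3, an early response gene, rose by 0.88 ± 0.10 with the block (SE, n = 3, adjusted p = 0.0143) and was the 1 member past over all tested probe sets there, with 0 without the block. Adjusted over the list alone 0 passed without the block, and with it 4 were higher, among them FOSL2 (0.72) and ERBB2 (0.58), and 1 was lower, KLF4 (-0.36). The call was lost with no filter (adjusted p = 0.142), without DMSO replicate 3 (0.207), without dioxin replicate 2 (0.423) and without experiment 2 (0.17). The mean of 0.20 became 0.10, 0.09, 0.08 and 0.10 in turn, and it was 0.32 without dioxin replicate 3. With the block, 2 were higher over all tested probe sets without experiment 1, and 0 were lower over the list alone without experiment 3.

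Ribosomal protein genes had a median log2 fold change of 0.11 with 15 of 16 above 0 (camera adjusted p = 4.37e-05, higher, and adjusted p = 0.412 with an estimated correlation), while their mean turned to -0.00806 after quantile normalization (adjusted p = 0.864). None of the 16 passed in limma over all tested probe sets or adjusted over the list alone, in either fit, with RPS23 at 0.21 and RPL8 at 0.17. Their mean of 0.12 was 0.07 without DMSO replicate 2, 0.19 without experiment 1 and 0.05 without experiment 2, where the call was lost (adjusted p = 0.122), and without experiment 1 there were 3 higher over the list alone with the block.

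**Figure D3:**
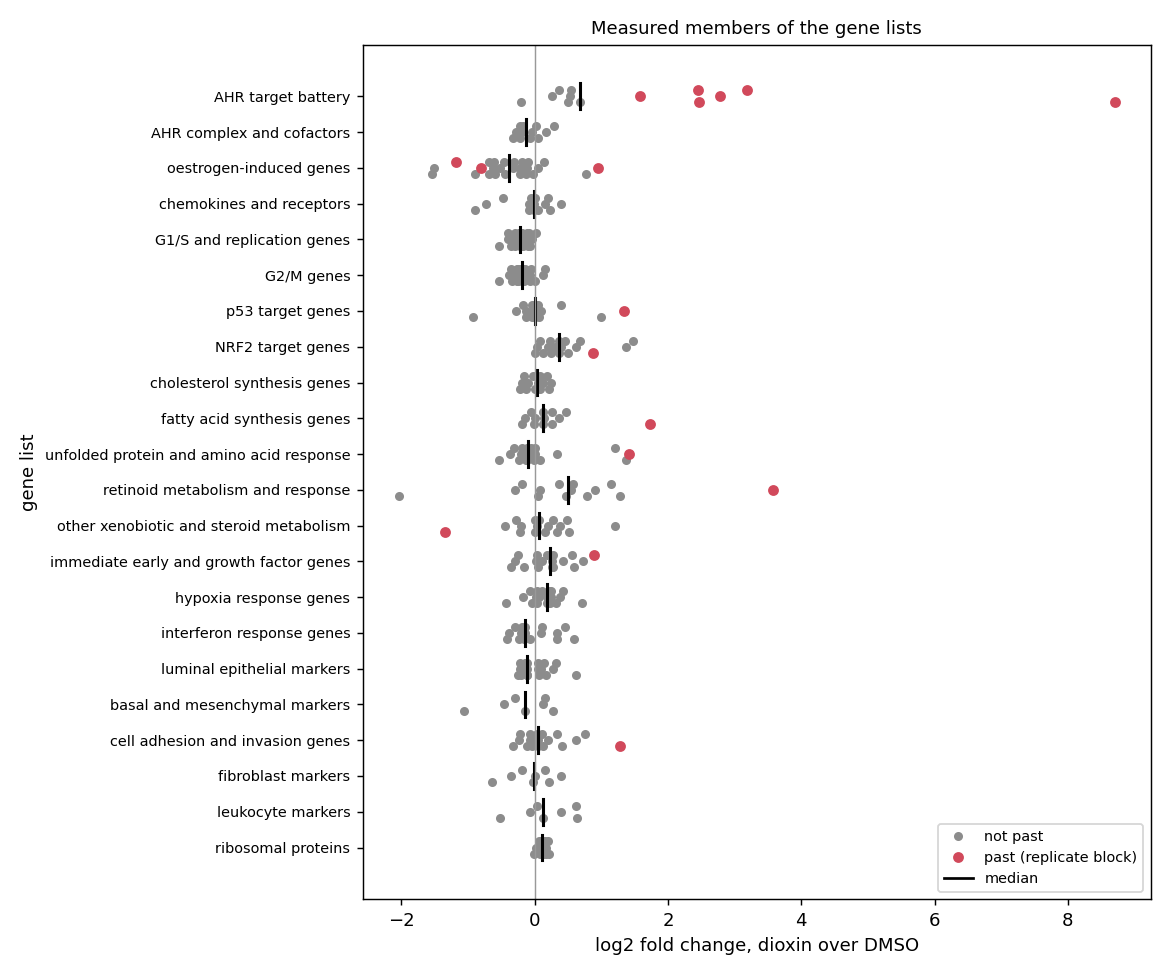
Log2 fold change of dioxin over DMSO for each measured gene of the 22 gene lists (points) and the list median (black bar); red points passed with the replicate block over all tested probe sets. The AHR target battery reached 8.70 and had a median of 0.67, against 0.51 for the retinoid list and -0.39 for the oestrogen-induced genes; the mean of the ribosomal proteins turned to -0.00806 after quantile normalization.

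The other lists did not pass in camera on U133A, and no member of them passed over all tested probe sets in limma without the block. Chemokines and their receptors had a median log2 fold change of -0.00654 (camera adjusted p = 0.302), and CXCL12 was the 1 of 14 lower when adjusted over the list alone, in both fits. For this list 1 was lower over all tested probe sets with the block without experiment 1. Targets of p53 had a median of -0.00140 and a mean of 0.07, with a camera direction of higher (adjusted p = 0.606). Among them GDF15, a stress-induced cytokine, rose by 1.34 ± 0.16 with the block (SE, n = 3, adjusted p = 0.0185), and adjusted over the list alone with the block GDF15 and GADD45A (1.00) were higher and PMAIP1 (-0.93) lower, where 0 of 17 passed without it. Without experiment 1 the blocked count of p53 targets over all tested probe sets was 2. The unfolded protein and amino acid list had a median of -0.10 and a mean of 0.09, with a camera direction of lower (adjusted p = 0.863); DDIT4 was the 1 of 20 higher over the list alone, and with the block it and SLC7A11 were. For that list, blocked counts were 2 higher over all tested probe sets in place of 1, and 1 lower over the list alone, without experiment 1, and 1 higher over the list alone without experiment 2.

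Lipid, hypoxia and foreign-compound lists also held few genes that passed. Cholesterol synthesis genes had a median log2 fold change of 0.03, a mean of 0.01 and a camera direction of lower (adjusted p = 0.771), with INSIG1 at -0.22, DHCR7 at -0.16, and 0 of 14 past in limma over the list alone in either fit. Fatty acid synthesis genes had a median of 0.12 (adjusted p = 0.0601); 0 of 13 passed over the list alone without the block and 2 were higher with it, PPARG and FASN (0.47). This list passed with the mean of a gene's probe sets (adjusted p = 0.0227), a filter at the 50th percentile (0.0361), without DMSO replicate 2 (0.0474), with the fluidics module as a random block (0.037), without dioxin replicate 2 (3.81e-04, mean 0.38 in place of 0.25) and without experiment 2 (1.12e-04, mean 0.38). Without experiment 3 its blocked counts were 0 over all tested probe sets and 1 over the list alone. Hypoxia genes had a median of 0.18 (adjusted p = 0.0601); 0 of 19 passed over the list alone without the block, and with it BHLHE40 (0.71) was higher and BNIP3 (-0.44) lower. The hypoxia list passed with a filter at the 50th percentile (adjusted p = 0.0499) and without dioxin replicate 1 (0.0207). Its blocked counts over the list alone became 0 lower without experiment 1, where 1 was higher over all tested probe sets, and 0 in each direction without experiment 2 or without experiment 3. Other xenobiotic and steroid enzymes had a median of 0.06, and a mean on U133A of 0.00438 (adjusted p = 0.959) that was -0.00565 after quantile normalization (adjusted p = 0.839). UGT2B15 was the 1 of 17 lower over the list alone in both fits and over all tested probe sets with the block. GSTM3 (0.52) was higher over the list alone with the block, and without experiment 2 no member passed over all tested probe sets.

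Interferon genes had a median log2 fold change of -0.15 (adjusted p = 0.606), with OAS3 at -0.39, IRF1 at 0.45, and 0 of 16 past in limma over the list alone in either fit; the list passed without dioxin replicate 1 (adjusted p = 0.0165). Adhesion and invasion genes had a median of 0.05 (adjusted p = 0.0678). NEDD9, a focal adhesion scaffold, rose by 1.27 ± 0.12 with the block (SE, n = 3, adjusted p = 0.00572), and adjusted over the list alone 0 of 19 passed without the block and 3 were higher with it, NEDD9, TIMP3 (0.76) and JUP (0.34). The adhesion list passed without DMSO replicate 2 (adjusted p = 0.0476), without dioxin replicate 2 (0.0294) and without experiment 2 (0.0406), and without experiment 3 its blocked count over the list alone was 1.

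Markers of cell types did not pass as lists. Luminal epithelial markers had a median log2 fold change of -0.11, a mean of 0.01 with a camera direction of lower (adjusted p = 0.863), and a mean of -0.03 after quantile normalization (adjusted p = 0.142), with KRT19 at -0.21. Adjusted over the list alone 0 of 19 luminal markers passed without the block and 1 was higher with it, ELF3 (0.62), and 0 without experiment 1. Basal and mesenchymal markers had a median of -0.15 (adjusted p = 0.08) with 7 of 20 measured, of which 0 passed over the list alone without the block and FN1 (-0.46) and CAV1 (-1.06) were lower with it. The basal list passed without DMSO replicate 2 (adjusted p = 0.0072), without dioxin replicate 1 (0.0446) and without experiment 2 (0.00363). Its blocked count over the list alone was 1 without any 1 of the experiments, and without experiment 1 there was 1 lower over all tested probe sets. Fibroblast markers had a median of -0.01, with THY1 at 0.39 and COL1A2 at -0.63, and leukocyte markers a median of 0.13, with CD2 at -0.52 and LCP2 at 0.63 (adjusted p = 0.863 for both lists). None of the 8 measured fibroblast and 7 measured leukocyte markers passed in limma over all tested probe sets or adjusted over the list alone, in either fit.

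Changes on U133A and U133B were compared where both measured the same item. Of 7 genes that passed with the block on U133A and were also tested on U133B, 5 had the same sign there, among them HEY2 at -1.38 and -0.57, TKT at 0.62 and 0.79, and TMEM164 at -0.67 and -0.52. NEDD9 (1.33 on its most changed U133A probe set and -0.08) and MYBL1 (-1.23 and 0.10) differed in sign, and 0 of the 7 passed on U133B in limma with the block. Across the 100 probe sets tested on both array types, the mean log2 fold changes had r = 0.56 and rho = 0.60, and r was 0.15, 0.21 and 0.40 in experiments 1, 2 and 3. Across 2773 genes measured by different probe sets r was 0.16 and rho 0.18. These are correlations across probe sets or genes, which are not independent replicates, and r of the shared probe sets was 0.32 without experiment 3.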

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

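The fits with the fluidics module, the blocked counts under other settings and the recomputed agreement of the array types were chosen after the data were seen. On U133A the random block by module cannot remove a module difference that goes with treatment, for probe sets or for lists. Scan day as a block was not run, since it coincides with the experiment number, hybridisation batch was not analysed here, and the robust variance model gave no list value, since camera does not use it. Of 99 named probe sets, 33 that did not pass without the replicate block passed with it, and the block changed no other call of a named probe set or list. Dim signals limit the fold changes of genes near the bottom of the arrays, such as CYP1A1 with DMSO, and CXCR4 and CYP26B1 with dioxin. Where a call changed with a setting, the cause was not tested, except that leaving out arrays leaves fewer samples.

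The U133A count of 8 was 4 with median centring, 0 in eBayes without trend (a variance prior that ignored signal) and 59 with the replicate block (37 higher, 22 lower); it was 6 with the fluidics module as a random block (correlation 0.298), 7 or 8 under the other settings, and 0 (without dioxin replicate 3) to 9 (without dioxin replicate 1) with arrays left out. The U133B count was 0 under every setting run other than the replicate block, which gave 12; the fluidics module as a block gave 0, in a fit that found 0 percent of simulated changes and so says nothing about stability. With the block, the U133A count of 59 was 39 with no filter, 0 in eBayes without trend, and 41 (without experiment 2) to 199 (without experiment 1). The U133B count with the block, 7 higher and 5 lower, was 4 with no filter, 4 with median centring (3 higher, 1 lower), 8 with quantile normalization (4 higher, 4 lower), 0 in eBayes without trend, and 13 (without experiment 2) to 41 (without experiment 1). The count of 8 gene lists, 8 with the block too, was 9 with the fluidics module as a random block, 1 with an estimated correlation and 1 with fry, which tests a list alone and does not compare it with other genes. Over the other settings, 871 values of named probe sets kept direction and call, 10 lost the call and 1 turned, and of list values 210 kept both, 15 lost the call, 4 gained it and 9 turned. With arrays left out, the 99 named probe sets gave 852 values that kept both, 28 that lost the call, 1 that gained it (SGK1) and 10 that turned, and the 22 lists 155, 7, 11 and 25. Only named probe sets of CYP1A1, CYP1B1, ALDH3A1, SLC7A5 and TIPARP had a call to lose, so most kept values were of uncalled probe sets. Of the 19 settings run, the call held in 15 for CYP1A1 and in 14 and 13 for the named CYP1B1 probe sets. It held in 13 for ALDH3A1, 12 for SLC7A5 and 9 for TIPARP. The agreement of the array types, r = 0.56, ran from 0.32 (without experiment 3) to 0.73 (without DMSO replicate 2).

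Several values turned sign, and none of them had passed except the ribosomal list. With quantile normalization the mean log2 fold change was -0.00806 for ribosomal proteins, -0.00565 for other xenobiotic and steroid enzymes and -0.0335 for luminal markers, and TFF1 was at -0.0699. With the mean of a gene's probe sets it was -0.0222 for the xenobiotic and -0.0305 for the luminal list. The xenobiotic list was at -0.0513 with no filter, and with a filter at the 50th percentile at -0.0765, with luminal markers at -0.00272 and cholesterol synthesis at -0.0125. With arrays or experiments left out, list means ran from -0.35 to 0.17 for chemokines, -0.0403 to 0.0697 for cholesterol synthesis, -0.158 to 0.0804 for xenobiotic enzymes, -0.33 to 0.21 for interferon genes, -0.0900 to 0.123 for luminal, -0.34 to 0.25 for fibroblast and -0.25 to 0.52 for leukocyte markers. Among genes the ranges were -0.24 to 0.14 for AHR, -0.0449 to 0.133 for ESR1, -0.0469 to 0.170 for TFF1 and -1.31 to 0.20 for COL1A2.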

Other observations

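The tests of the antioxidant list, of the oestrogen-induced list, and of RNA quality, chip lot and scan day were chosen only after the result was seen, while the splits of the arrays and the test of scaling were not.

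Some genes outside the naming rule were picked after their values were seen, all from the fit with the replicate block on U133A. SLC3A2, the heavy chain that pairs with SLC7A5 in the amino acid transporter, rose by 1.08 ± 0.15 (SE, n = 3, limma adjusted p = 0.0362). ABCG2, an efflux transporter, rose by 1.28 ± 0.20 (adjusted p = 0.0469), and TRIM16 rose by 0.96 ± 0.10 (adjusted p = 0.00822). DKK1, a secreted inhibitor of WNT signalling, gave -0.89 ± 0.09 (adjusted p = 0.00822), and its adjusted p without the block was 0.0856.

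Other splits of the arrays were too few for a share under 0.05. On U133A the real split gave 8 probe sets against a highest of 0 among the other splits (1 of 10 splits gave as many), and with the block 59 against 0 (1 of 4). It gave 8 gene lists against 2 to 6 in every other split (1 of 10 gave as many). Camera with the preset correlation thus also called lists when the treatments were mixed between the groups. On U133B all 10 of 10 splits gave 0, and with the block the real split gave 12 against 0 (1 of 4). The split with 6 lists set DMSO 1, dioxin 2 and dioxin 3 against the rest and parts all 3 pairs, as the real one does.

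The antioxidant genes of the NRF2 list were highest in experiment 2. For the rise of the list in experiment 2, a signal-dependent bias between its arrays is argued against. Over the 17 list genes on U133A the mean of 0.81 lay at percentile 100 of 10000 random lists matched on signal (random lists -0.15 to 0.19). The list also lay at percentiles 99.76 and 99.63 in experiments 1 and 3, so the test does not address the excess of experiment 2. Its random lists drew genes singly, while the list had an estimated correlation of 0.49. A fault of 1 U133A hybridisation stays open: over the 4 list genes on U133B the excess of experiment 2 over the others was -0.00661 ± 0.44 (SE across genes), an interval that holds both 0 and the U133A excess of 0.54 ± 0.18 (SE across genes). Those SEs take genes as independent. The excesses of the 4 genes on U133B were 1.22 for SRXN1, -0.08 for ABCC3, -0.30 for TKT and -0.86 for GCLM. The rule of that test was changed after its outcome was seen: by the first rule a mean excess at or below 0 counted for a fault, so the same value did. A biological difference between the experiments was not tested, because the labels name none.

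The oestrogen-induced genes shifted lower as a list in camera, with an adjusted p of 0.091 with an estimated correlation and 0.0856 in fry; 0 of 26 passed in limma over all tested probe sets without the block, and STC2 (0.95) and MYC (0.76) lay above 0. A signal-dependent bias is argued against by a list mean on U133A of -0.39 at percentile 0 of 10000 matched random lists (random lists -0.09 to 0.11), whose genes were drawn singly. A lower ESR1 transcript level is argued against too on its brightest probe set, where the lower end of the 95% interval of the change was -0.14, above the list median of -0.33 on U133A. The dimmer ESR1 probe sets tested lay between -0.48 and 0.57, and none passed in either fit. That rule assumes that the targets fall no more than the ESR1 transcript. Fewer dividing cells stay open as an explanation, because the cell cycle genes lay above the oestrogen-induced genes by 0.18 with an SE across genes of 0.12. That SE takes genes as independent, while camera estimated correlations of 0.29 and 0.39 within the G1/S and G2/M lists. An action of dioxin on oestrogen receptor target genes is a hypothesis left untested, since deciding it would need dioxin with and without oestradiol or AHR, and the groups here were DMSO and dioxin alone.

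The arrays of experiment 1 stood apart from those of experiments 2 and 3. Trimmed-mean scaling is argued against as the cause, since after quantile normalization the highest r of an experiment 1 array with the others stayed under the lowest between experiments 2 and 3 by 0.023 on U133A and 0.0767 on U133B. RNA degradation in experiment 1 is argued against by 0 of its 8 GAPDH and ACTB ratios lying above the range of the other experiments. Chip lot and scan day cannot be told apart from the experiment, as 0 lots or days were shared by experiments. The fluidics module followed the same divide on both array types. Arrays of experiment 1 were on modules 3 and 4, and those of experiments 2 and 3 on modules 1 and 2. Module and experiment 1 thus cannot be told apart either, and the module was not tested as the cause.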
